A study of Mus musculus with 6 samples.

How the data were processed

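RNA was measured in Melb-a cells, an immortal mouse melanoblast line, after 48 h in a differentiation medium that held either the vehicle DMSO or 10 µM iBRD9. There were 3 independent samples per treatment, per the labels. Total RNA was extracted with TRIzol and a column kit, poly(A) RNA was selected with oligo-dT beads, and libraries were primed with random hexamers, per the labels' protocols. The kit named there is not described as marking strand, so reads of overlapping and antisense genes cannot be told apart.

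The deposited table holds raw read counts per Ensembl gene ID, made by the authors from their reads. CASAVA 1.8.2, Bowtie2 2.4.5 and the genome build GRCm39 are named in the submitters' processing notes. The counting program, the annotation release, the strand setting and any filter on reads are not given in the sources used here. The values were whole numbers with a different total in each library, from 22846391 to 29680952, and were used as counts without change. The table has 35275 gene IDs, of which 34490 were matched to a symbol. The 785 IDs without a symbol held 0.0899% of all counts. The reference annotation at hand is of an older build than the one the authors named, so it served for gene names only and no coordinates are given. Genes with closely related copies or pseudogenes are uncertain wherever the authors' counting split their reads.

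Samples were grouped by the treatment in their labels, and iBRD9 was compared with DMSO using all 6 libraries. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 13602 tested genes, while 12626 genes had 0 counts in every library. Libraries were scaled by the trimmed mean of M values (TMM). The edgeR quasi-likelihood F-test with robust dispersion estimation was run in edgeR 4.0.16 under R 4.3.3, with treatment as the sole term, and p-values were adjusted by the Benjamini-Hochberg method. A gene is called at an adjusted p under 0.05. Expression values are TMM-scaled CPM, given as the mean ± SD of 3 libraries, and the standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. All tests are two-sided. The biological coefficient of variation was 0.0921.

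Before the data were examined, 27 gene lists were fixed, covering pigment production, melanocyte regulators, SWI/SNF subunits, the cell cycle, stress, immune, metabolic and signalling genes, matrix, and markers of other cell types. For each list the called members were counted. The 26 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The test was repeated with an estimated correlation, and with fry. Genes are named by a rule with 3 parts, fixed at the same time. The first takes the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 2, non-overlapping groups and a symbol that is not a predicted model. The second holds Tyr, Tyrp1, Dct, Pmel, Mlana, Mitf, Sox10, Slc45a2, Oca2, Mc1r, Kit, Brd9, Brd7 and Smarca4 whatever their values. The third takes from each list up to 2 higher and 2 lower called members with the largest change and a mean log2 CPM of at least 1. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen, and is marked so.

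The procedure was first tested on simulated counts drawn from the means and depths of these libraries over 13396 genes. For the simulated comparison of iBRD9 with DMSO, 83 of 97 genes changed by 2-fold were recovered (85.6%) and 68 of 100 changed by 1.5-fold. Of the calls, 6.70% were genes that had not been changed, and none of the other lists was called beside the shifted one (0 of those tested). Each gene was drawn on its own, so the simulated genes of a list were not correlated. The list result therefore does not test the preset correlation on the real lists, where the estimated correlation reached 0.945 for cholesterol biosynthesis. These figures describe the precision at this depth with 3 libraries per group where few genes change. In the real comparison 60.7% of tested genes were called, which shifts the cutoff of the adjusted p, so recovery there may differ. No replicate pair was a duplicate: the chi-square per degree of freedom between libraries of a group ran from 1.93 to 37.5 over genes with at least 20 counts in the pair.

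The alternatives were DESeq2 size factors in edgeR, library size alone, DESeq2 1.42.0 with its Wald test, limma-voom, no filter beyond removing genes at 0, a filter at 1 CPM in at least 3 libraries, the replicate number as a block, an adjusted p under 0.01, and leaving out each library in turn. Exact permutation tests of library composition cannot give a p below 0.1 with 3 against 3 libraries. Figures were drawn with matplotlib 3.10.9. No column of the deposited table was left out.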

Results

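The data are RNA-seq read counts of mouse Melb-a melanoblasts, a line from C57BL/6J skin that makes melanin once it is moved from growth medium to differentiation medium. All cells received DMEM with 10% serum, 2 nM of the α-melanocyte stimulating hormone analog NDP-α-MSH, which acts on the receptor Mc1r, and 200 nM of the phorbol ester PMA, an activator of protein kinase C. For 48 h the medium also held DMSO (3 samples) or 10 µM iBRD9 (3 samples). iBRD9 binds the bromodomain of BRD9, a subunit of a form of the SWI/SNF chromatin remodeling complex, and the series is about the control of pigmentation by SWI/SNF. The DMSO libraries held 23248475, 26675006 and 24986925 counts and the iBRD9 libraries 29680952, 24134176 and 22846391. Mitochondrial transcripts took 3.53% ± 0.159 of counts with DMSO and 2.77% ± 0.329 with iBRD9 (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allow), and 18260 ± 30.4 and 19074 ± 279 genes had a count.

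The comparison asks which transcripts differ between cells given iBRD9 and cells given DMSO during differentiation. A single compound was used at a single dose, so effects through BRD9 cannot be told apart from other effects of the compound. Tyrosinase (Tyr, ENSMUSG00000004651), the rate-limiting enzyme of melanin synthesis, fell from 537 ± 14.5 CPM with DMSO to 87.8 ± 3.72 CPM with iBRD9 (SD, n = 3), a log2 fold change of -2.61 (SE 0.060, adjusted p = 1.44e-07). Among the 10 largest falls were Nupr1 (-3.98), a stress-induced chromatin protein, and Slc7a11 (-3.91), the cystine transporter. Trib3 (-3.62) and Chac1 (-3.53), both induced by the transcription factor ATF4, were also among them. Further falls were in the complement gene C4b (-3.79), Cyp4b1 (-3.63), the monocarboxylate transporter gene Slc16a7 (-3.26), the retinal reductase gene Dhrs3 (-3.07) and the carbonic anhydrase gene Car14 (-3.07). The largest rise by the naming rule was in the cytosolic chaperone gene Hsp90aa1 (ENSMUSG00000021270), from 29.7 ± 3.30 to 802 ± 56.2 CPM, a log2 fold change of 4.75 (SE 0.103, adjusted p = 1.44e-07).

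Other large rises were in Ccdc8 (4.51), the imprinted noncoding RNA H19 (4.26) and keratin 7 (Krt7, 4.07). Further ones were in the type VII collagen gene Col7a1 (3.81), Flrt1 (3.74), Rrp1 (3.53), Hspa12a (3.52) and Rrp15 (3.45). Several of these were near the floor with DMSO, with Krt7 at 0.436 ± 0.194 CPM and Ccdc8 at 0.363 ± 0.241 CPM, while H19 went from 2.37 ± 0.510 to 45.4 ± 10.4 CPM. Hsp90aa1 has pseudogene copies and C4b a closely related copy, so their counts are uncertain where reads are shared. Hsp90aa1 was low in every DMSO library (26.3 to 32.9 CPM), and the design cannot separate a response to iBRD9 from a difference in how the reads of the groups were processed. Rrp1 and Rrp15 belong to a set of genes named for ribosomal RNA, chosen after their values were seen, that were low in every DMSO library: all 9 tested members were higher with iBRD9, by 1.67 to 3.53 on the log2 scale.

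In all, 8262 of 13602 tested genes were called, 60.7% of them, with 4057 higher and 4205 lower with iBRD9. At least 2-fold changes were found in 1280 genes that rose and 742 that fell. The balance of directions varied with abundance: of all calls, 432 were higher and 152 lower at a mean log2 CPM below 0, against 163 and 339 above 8. The groups did not overlap in 8126 of the called genes, and in 68.0% of all tested genes, where chance gives 10%. Scaling by library size alone gave 4999 higher and 3385 lower calls, since it moved the median log2 fold change by 0.106. DMSO replicate 1 stood apart from the other DMSO libraries: over 378 genes that were at least 2-fold lower with iBRD9 than in DMSO replicates 2 and 3, it had moved a median fraction of 0.362 of the way to iBRD9. Without it, 10311 genes were called.

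**Figure D1:**
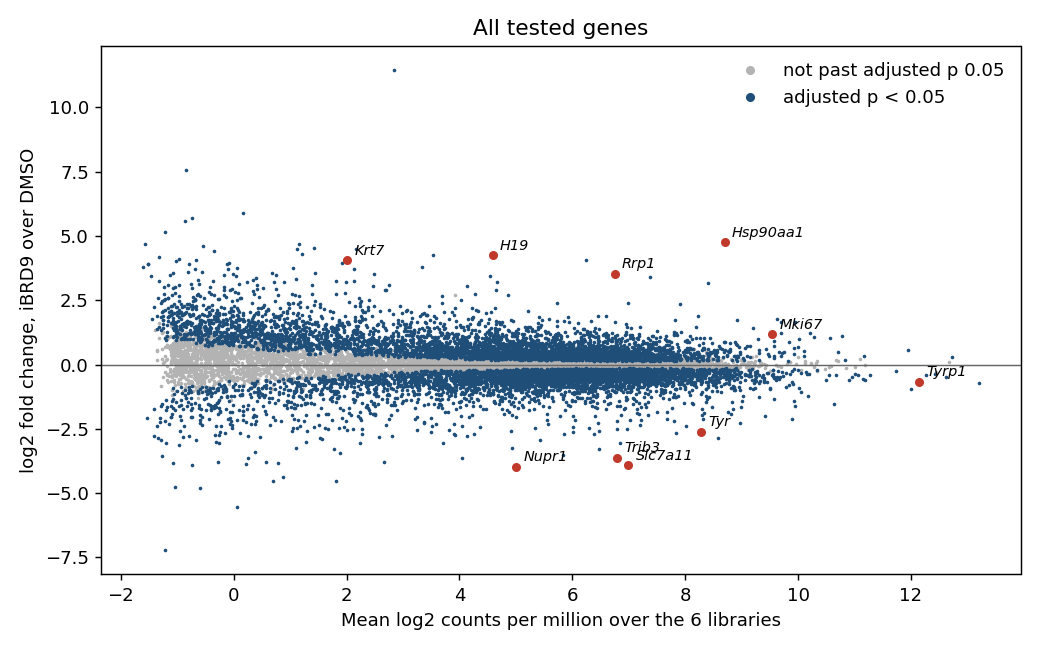
Log2 fold change of iBRD9 over DMSO (vertical axis) against the mean log2 CPM (horizontal axis) for the 13602 tested genes, with called genes in blue, the others in grey and 10 named genes in red. Tyr lies at -2.61 and Hsp90aa1 at 4.75; the point above 10 is Gm10275, which had 0 reads with DMSO, so its fitted fold change is no measure of size.

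Most of the called pigment genes fell, and some rose. Of the 18 tested members of the list of melanin synthesis and melanosome proteins, 10 fell, 3 rose and 5 did not pass the test. Besides Tyr and Slc7a11, the melanosomal transporter genes Slc45a2 (1618 ± 183 to 694 ± 50.7 CPM, log2 fold change -1.22) and Oca2 (2.77 ± 0.648 to 0.915 ± 0.102 CPM, -1.59) fell. Oca2 was near the floor. The melanin enzyme gene Tyrp1 (5576 ± 408 to 3517 ± 186 CPM, -0.66), the melanosome protein gene Mlana (-0.62) and the hormone receptor gene Mc1r (-0.67) fell by less. Dct, another enzyme of the pathway, rose from 6074 ± 394 to 7525 ± 450 CPM (0.31, adjusted p = 0.00959), as did Mfsd12 (0.59). Tpcn2, the other risen member (0.39, adjusted p = 0.0239), passed with all libraries and without DMSO replicate 1, and did not pass without any 1 of the other libraries (0.29 without DMSO replicate 2 to 0.42 without iBRD9 replicate 2). Pmel, the gene of the melanosome fibril protein, had a log2 fold change of 0.20 (adjusted p = 0.0920) and passed with library size alone (0.31, adjusted p = 0.0106, the lowest of its alternatives, which ran up to 0.275). The list's median log2 fold change was -0.54, with a camera adjusted p of 0.0504, just outside the threshold, and an adjusted p of 0.770 with an estimated correlation. It passed with DESeq2 size factors (0.0498), with library size alone (0.0336), without a filter (0.00676), with fry (0.00254), without DMSO replicate 1 (0.0398) and without iBRD9 replicate 1 (0.0278), and its adjusted p ran from 0.00254 to 0.770 over all alternatives.

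**Figure D2:**
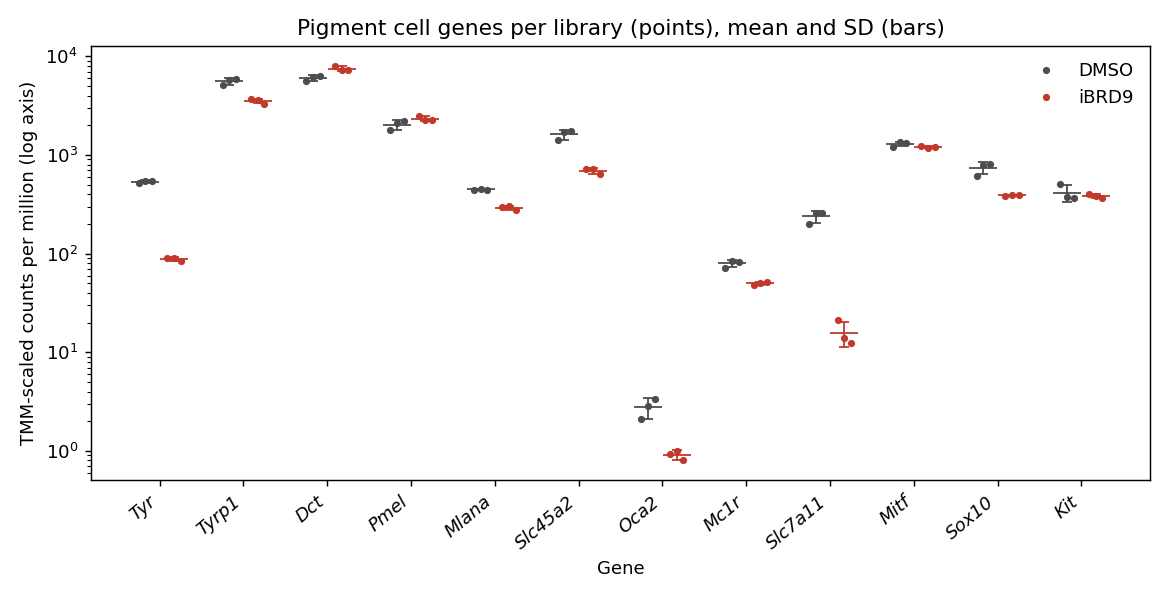
TMM-scaled CPM on a log axis for 12 pigment cell genes, with 1 point per library and bars for the mean and SD of 3 DMSO (grey) and 3 iBRD9 (red) libraries. Tyr falls from 537 to 87.8 and Slc7a11 from 239 to 15.8, while Dct is slightly higher with iBRD9 and the groups overlap for Mitf and Kit.

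Of the 26 tested genes of melanosome biogenesis and transport, 12 fell and 4 rose (median -0.19, camera adjusted p = 0.107). The small GTPase genes Rab38 (332 ± 94.4 to 75.6 ± 1.92 CPM, -2.13) and Rab32 (321 ± 38.7 to 90.3 ± 3.95 CPM, -1.83), which direct cargo to melanosomes, had the largest falls. Rab27a, which links melanosomes to the motor, also fell (-1.49), while the motor gene Myo5a rose from 990.5 ± 45.0 to 2031 ± 118 CPM (1.04) and Snapin by 0.52 on the log2 scale.

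Most regulators of the melanocyte lineage fell, Mitf and Kit not among them: 10 of 13 tested members fell, none rose (0) and 3 did not pass (median -0.82, camera adjusted p = 0.00275, adjusted p = 0.640 with an estimated correlation). Erbb3, a receptor of neural crest cells, fell from 151 ± 4.52 to 53.1 ± 6.72 CPM (-1.51), the transcription factor gene Irf4 from 57.8 ± 5.20 to 24.9 ± 2.19 CPM (-1.21), and Sox10, which specifies the lineage, from 739 ± 104 to 390.4 ± 4.08 CPM (-0.92). Mitf, the master regulator of pigment genes, stood at 1297 ± 70.7 and 1206 ± 33.8 CPM (-0.10, adjusted p = 0.184). Kit, the receptor of stem cell factor, stood at 415 ± 80.8 and 384 ± 18.2 CPM (-0.11, adjusted p = 0.448). Without DMSO replicate 1, Mitf passed (-0.16, adjusted p = 0.00374, with 0.00374 to 0.979 over all alternatives), 1 regulator rose and Kit had a value of 0.05; with library size alone Mitf had a value of 0.00. Among 14 tested targets of MITF outside pigmentation, 7 fell and 5 rose (median -0.13, with -0.08 without DMSO replicate 3 and -0.20 without iBRD9 replicate 3; camera adjusted p = 0.685), with Cdk2 up 1.17 and Bcl2 up 0.39, and Rab27a and Cdkn1a (-1.28) down.

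Markers of Schwann cells, which share a neural crest origin with melanocytes, fell throughout. All 8 tested markers were lower, S100b among them (91.0 ± 23.9 to 26.4 ± 1.16 CPM, -1.78). The median was -1.62, with a camera adjusted p of 0.00108 and an adjusted p of 0.640 with an estimated correlation. Of 11 tested genes of the neural crest and dedifferentiated state, 8 fell and 2 rose (median -0.74, camera adjusted p = 0.0304, adjusted p = 0.641 with an estimated correlation). Zeb1 (-1.95) and Aqp1 (-1.20) had the largest falls, and the intermediate filament gene Nes rose (0.53). Tfap2b also rose (0.53, adjusted p = 0.0135), but did not pass without iBRD9 replicate 3 (0.44, adjusted p = 0.0607, the highest of its alternatives, with 0.000485 the lowest), which left 1 gene of the list called higher.

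Brd9 itself did not pass the test, with 37.4 ± 4.07 CPM in DMSO and 38.8 ± 0.0510 CPM in iBRD9 (log2 fold change 0.05, SE 0.085, adjusted p = 0.624). Of the 28 SWI/SNF subunit genes tested, 10 rose and 5 fell (median 0.11, camera adjusted p = 0.308). Bicra, whose protein shares the complex with BRD9, rose from 11.8 ± 1.09 to 20.7 ± 1.13 CPM (0.81), as did Ss18l1 (0.82) and the ATPase gene Smarca4 (0.36, SE 0.062, adjusted p = 0.00123). Phf10 (-0.82) and Bcl7b (-0.61) fell, as did Brd7, a subunit of another form of the complex (-0.25, adjusted p = 0.00750). The value for Brd9 was -0.04 without DMSO replicate 3, and Brd7 did not pass with library size alone (-0.15, adjusted p = 0.0506, with 7.04e-06 to 0.0506 over all alternatives).

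More cell cycle genes rose than fell. In S phase and DNA replication 10 of 24 tested genes rose and 1 fell (9 and 1 adjusted over the list alone), and in G2 and mitosis 13 of 24 rose and 1 fell. The proliferation marker Mki67 rose from 459 ± 40.0 to 1036 ± 35.5 CPM (1.18), the mitotic kinesin gene Kif23 by 0.96 on the log2 scale, and the cyclin gene Ccne2 (1.19) and the histone mRNA binding protein gene Slbp (0.83) likewise. Ung (-0.56) and Aurka (-0.28) were the members that fell, and Aurka did not pass with library size alone (-0.18, adjusted p = 0.0525, with 2.80e-05 to 0.0525 over all alternatives). The medians were 0.24 in both lists, each with a camera adjusted p of 0.0504 and of 0.770 with an estimated correlation. Without DMSO replicate 1, 16 S phase genes rose and 4 fell, and 3 G2 and mitosis genes fell.

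In the list of ATF4 and the unfolded protein response more genes fell than rose. Of 17 tested members, 10 fell and 4 rose (median -0.73, camera adjusted p = 0.102). Trib3 went from 206 ± 42.0 to 16.6 ± 6.84 CPM and Chac1, which degrades glutathione, from 105 ± 17.5 to 8.89 ± 5.01 CPM. Creld2 rose (0.81), and so did the chaperone gene Hspa5 (0.90, adjusted p = 0.0164), which stood at 973, 506 and 433 CPM in the DMSO libraries and did not pass without a filter (0.89, adjusted p = 0.147), without DMSO replicate 2 (0.75, adjusted p = 0.0587) or without iBRD9 replicate 1 (0.90, adjusted p = 0.0529), with 4.75e-15 to 0.147 over all alternatives. The count of risen members was 7 without DMSO replicate 1, and 2 without DMSO replicate 2 or without iBRD9 replicate 1. Among 17 tested p53 targets, 11 fell and 2 rose (median -0.39, camera adjusted p = 0.0504). Gdf15 (5.05 ± 1.72 to 0.710 ± 0.234 CPM, -2.85) and Sesn2 (247 ± 9.91 to 47.9 ± 12.8 CPM, -2.36), which the ATF4 list holds as well, had the largest falls. The growth arrest gene Btg2 (1.31) and Sesn1 (0.47) rose, and 7 targets fell without iBRD9 replicate 2.

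More genes of energy metabolism fell than rose. In oxidative phosphorylation 18 of 25 tested genes fell and 3 rose (median -0.43, camera adjusted p = 0.00676, adjusted p = 0.688 with an estimated correlation), with Ndufs8 (-0.66) and Atp5b (2791 ± 273 to 1838 ± 32.6 CPM, -0.60) down and Cox7b (0.40) and Ndufa4 (0.37) up. In glycolysis and the hypoxia response 11 of 16 fell and 1 rose, the glucose transporter gene Slc2a1 (0.32), against 12 and 1 adjusted over the list alone (median -0.47, camera adjusted p = 0.0118, adjusted p = 0.640 with an estimated correlation). Vegfa (-0.97) and the glycolytic enzyme gene Pfkp (169 ± 1.34 to 92.2 ± 0.295 CPM, -0.88) fell the most. Slc2a1 did not pass without DMSO replicate 2 (0.23, adjusted p = 0.0541) or without iBRD9 replicate 3 (0.28, adjusted p = 0.0638, with 1.47e-06 to 0.0638 over all alternatives), which left 0 genes called higher, and 2 were called higher without DMSO replicate 3. In the lysosome list 12 of 20 fell and 2 rose (12 and 3 adjusted over the list alone; median -0.26, camera adjusted p = 0.0951), with the autophagy receptor gene Sqstm1 (-1.43) and Gla (-1.09) down and Neu1 (0.45) and Ctsl (0.42) up; 4 rose without DMSO replicate 1.

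Values for cholesterol synthesis genes moved with single libraries. Of 20 tested, 4 rose and 2 fell (3 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 0.180), and without DMSO replicate 1 17 rose and 2 fell, with a median of 0.69, against 3 and 3 with a median of 0.15 without DMSO replicate 3. Insig1, which holds back sterol synthesis, stood at 651, 305 and 231 CPM in the DMSO libraries and 1264 ± 66.4 CPM with iBRD9 (1.67, adjusted p = 0.00247). It did not pass without a filter (adjusted p = 0.0542, with 0.000179 the lowest of its alternatives), and the calls of Nsdhl (-0.59) and Fdps (-0.37) were lost in some settings. No member was called lower (0) without iBRD9 replicate 1 (-0.56 and -0.32) or without iBRD9 replicate 2 (-0.58 and -0.40), and 1 was called lower without DMSO replicate 2 or without iBRD9 replicate 3.

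Most interferon response genes fell: 11 of 19 were lower and 1 was higher (median -0.52, camera adjusted p = 0.00676, adjusted p = 0.640 with an estimated correlation). The guanylate binding protein gene Gbp3 (-1.24) and Irf9 (24.8 ± 2.78 to 10.9 ± 1.07 CPM, -1.18), a subunit of the interferon-activated complex, were lower, and Stat2, of the same complex, was higher (0.50). Of 13 tested antigen presentation genes 8 fell and 2 rose (median -0.41, camera adjusted p = 0.0649), with the peptidase gene Erap1 (-0.78) and the immunoproteasome gene Psmb10 (-0.77) down. The count of risen genes was 1 without DMSO replicate 3 and 0 without iBRD9 replicate 1.

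Signalling genes went both ways. Of 19 feedback and immediate early genes of the MAPK pathway, 7 fell and 3 rose (7 and 2 adjusted over the list alone; median -0.21, camera adjusted p = 0.387), with Etv4 (-1.91) and Myc (70.8 ± 11.1 to 35.6 ± 2.65 CPM, -0.99) down and Spry2 (0.97) up. In that list 6 rose without DMSO replicate 1, 1 rose without DMSO replicate 2 or without iBRD9 replicate 3, and 4 fell without the last; its median was -0.13 without DMSO replicate 1 and -0.10 without iBRD9 replicate 1. Of 13 cAMP response genes, 5 fell and 3 rose (6 and 4 adjusted over the list alone; median -0.01, and -0.11 without DMSO replicate 3 to -0.002 without iBRD9 replicate 2, moved over 1.5 times by each library; camera adjusted p = 0.578). Their nuclear receptor genes parted: Nr4a3 fell from 771 ± 62.8 to 244 ± 11.1 CPM (-1.66), while Nr4a1 (1.05) and Nr4a2 (0.88) rose, and the phosphodiesterase gene Pde4d fell (-1.73). Of 10 Wnt targets, 4 fell and 2 rose (median -0.38, and -0.16 without DMSO replicate 1; camera adjusted p = 0.578), with Tnfrsf19 (-2.70) down and the Wnt inhibitor genes Nkd1 (2.13) and Znrf3 (0.64) up.

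Of 20 MYC targets and ribosome biogenesis genes, 5 rose and 5 fell (median 0.08, with 0.05 without DMSO replicate 1 or without iBRD9 replicate 2 and 0.13 without iBRD9 replicate 1; camera adjusted p = 0.725); the rises were led by Rrp12 (3.20) and Rrp9 (2.49), of the set that was low in every DMSO library, and Wdr43 (-0.62) and Polr1b (-0.59) fell. Of 12 genes of the xenobiotic and NRF2 response, 7 fell and 2 rose (7 and 3 adjusted over the list alone; median -0.32, camera adjusted p = 0.134). Besides Slc7a11, Gstm1 fell (128 ± 10.9 to 45.5 ± 0.881 CPM, -1.49), and the drug efflux pump gene Abcb1b (0.98) and Gclc (0.47) rose. Of 18 matrix and adhesion genes, 7 rose and 7 fell; the median was -0.15 and the mean 0.04, which differ in sign, and camera's direction was down (adjusted p = 0.707). The collagen gene Col5a1 (21.8 ± 5.56 to 73.7 ± 3.21 CPM, 1.76) and the integrin gene Itgb3 (1.45) rose, and Mmp2 (-1.43) and Tgfbi (-0.99) fell.

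The lists of markers of cell types besides Schwann cells had from 2 to 8 tested members. Of 4 tested keratinocyte markers 2 fell and none (0) rose (median -0.58, camera adjusted p = 0.183), namely Cdh1 (-1.89), the cadherin by which melanocytes bind keratinocytes, and Itgb4 (-1.19). Of 8 fibroblast markers 2 rose and 2 fell (median 0.03, camera adjusted p = 0.912). The median ran from -0.02 without DMSO replicate 2 to 0.10 without DMSO replicate 1, and was moved over 1.5 times by each library. Col1a1, near the floor with DMSO (0.679 ± 0.0336 to 3.52 ± 0.877 CPM, 2.36), and Dcn (51.2 ± 7.38 to 120.5 ± 7.09 CPM, 1.23) rose, while Col1a2 (-1.95) and Fbln1 (-0.47) fell. Of 4 macrophage and leukocyte markers 1 rose and 1 fell, Cd68 (-0.69), with a median of 0.07 (0.02 without DMSO replicate 3, 0.11 without iBRD9 replicate 2 and 0.01 without iBRD9 replicate 3; camera adjusted p = 0.920) and 2 lower without DMSO replicate 1. The endothelial list had 2 tested members and no set test, with Kdr higher (0.941 ± 0.157 to 3.98 ± 1.01 CPM, 2.07) and Vwf lower (-1.10).

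Camera with the preset correlation called 6 of the 26 lists, while with an estimated correlation it called 0 (lowest adjusted p = 0.640, and 0 lists at an unadjusted p under 0.05), and fry, which asks if a list's genes move on balance one way without comparing them with other genes, called 20. The correlation was estimated from 3 libraries per group, DMSO replicate 1 among them, and reached 0.945 for cholesterol biosynthesis. With it, camera did not call even the Schwann cell list, whose 8 tested members were all called lower. Its lack of calls therefore cannot show that no list moved. For the 6 lists called with the preset, the estimate ran from 0.180 (interferon response) to 0.297 (oxidative phosphorylation), above the preset 0.01. Their p-values with the preset may therefore be too small, so these 6 calls are uncertain as well. Leaving out DMSO replicate 1 gave 14 called lists, adding melanin synthesis, melanosome biogenesis, S phase, mitosis, p53 targets, antigen presentation, cholesterol synthesis and the lysosome. Leaving out iBRD9 replicate 1 gave 11, adding melanin synthesis, S phase, mitosis, p53 targets and the ATF4 list. Where no other count is given, the counts adjusted over the list alone were equal to those over all genes tested.

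**Figure D3:**
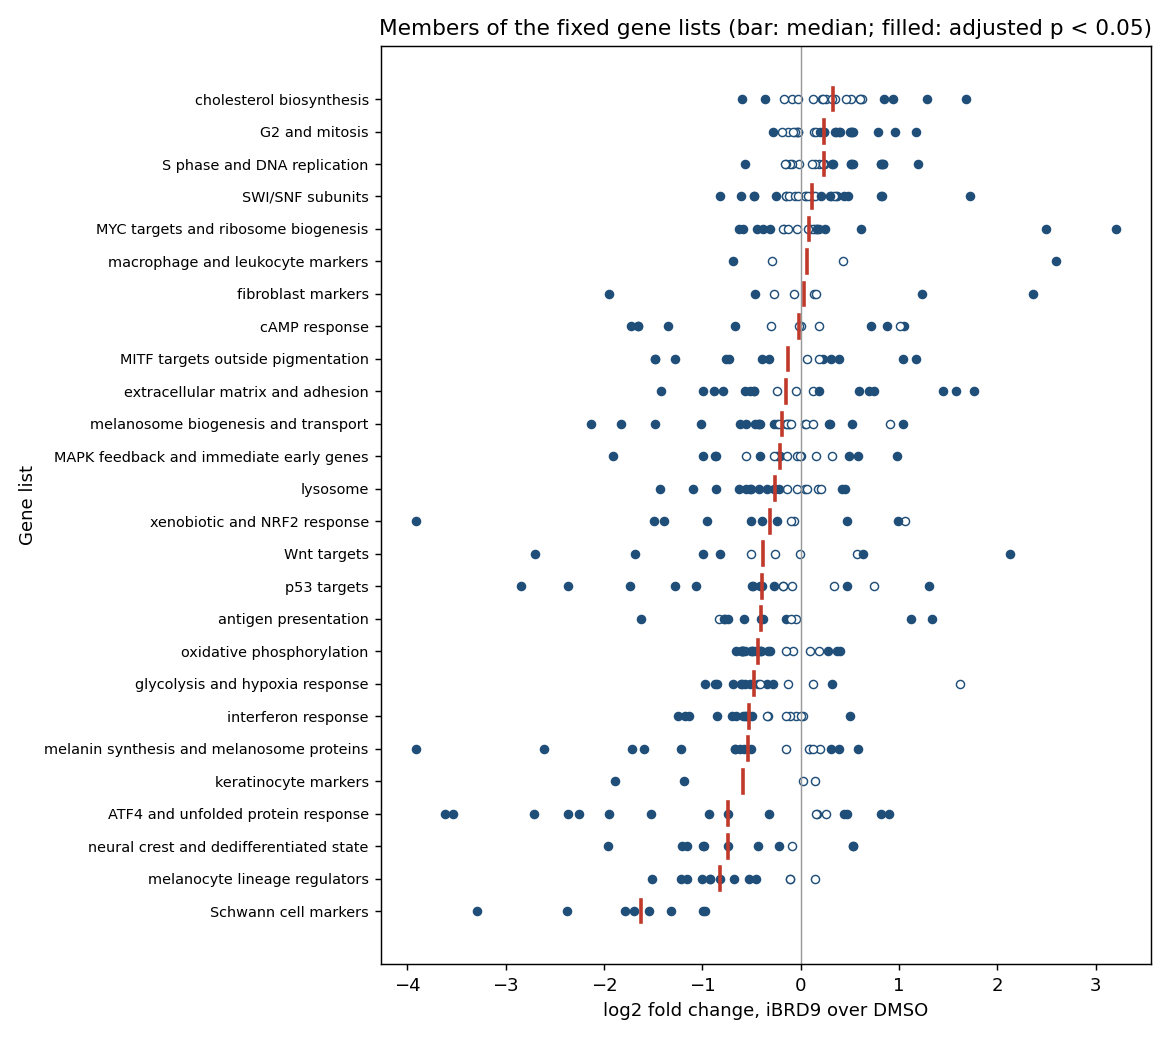
Log2 fold change of iBRD9 over DMSO (horizontal axis) for each tested member of the 26 gene lists with a set test (vertical axis), with filled points for called genes, open points for the others and a red bar for the list's median. Lists are ordered by the median, from -1.62 for Schwann cell markers to 0.33 for cholesterol biosynthesis.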

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

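The 5 counts of called genes stayed within 1.5 times their reported values under each alternative. Over all of them the total ran from 6072 at an adjusted p under 0.01 to 10311 without DMSO replicate 1; DESeq2 called 7988 genes, of which 7899 were among the 8262, limma-voom 8368, and the stricter filter 7794. The samples share only a number: their same-numbered deviations from the group means correlated across genes at 0.0756, 0.183 and 0.0317, so the numbers were not taken as pairs. Every library did correlate best with the library of its own number in the other group. The correlations are small, and with 3 numbers such a match can readily come by chance, so it is at most a weak hint. With the replicate number as a block 7937 genes were called. The melanin list kept its direction in each setting; its median of -0.54 with fry and with DESeq2 size factors, -0.43 with library size alone and -0.55 without a filter came with a passed threshold, and leaving out single libraries gave medians from -0.60 to -0.48. In place of 6 called lists, there were 0 with an estimated correlation, 20 with fry, 10 with DESeq2 size factors, 11 with library size alone, 15 without a filter, 10 with the stricter filter, and from 6 to 14 when single libraries were left out (14 without DMSO replicate 1, 11 without iBRD9 replicate 1). Of the lists not called, 4 lay at an adjusted p of 0.0504, next to the threshold; the cause of the moves was not tested. Medians of lists changed sign in MITF targets (0.0907) and macrophage markers (-0.27) with the stricter filter, cAMP response (0.0911) with library size alone, matrix genes (0.15) and keratinocyte markers (0.54) without a filter, and fibroblast markers without DMSO replicate 2 (-0.0226) and without DMSO replicate 3 (-0.00921), with a range of -0.0226 to 0.0967 over left-out libraries. Genes that changed sign were Mitf (0.00187) with library size alone, Kit without DMSO replicate 1 (range over left-out libraries -0.208 to 0.0512) and Brd9 without DMSO replicate 3 (range -0.0364 to 0.116). With all 6 libraries and TMM none of these genes was called, nor any of these lists by camera. Fry did call the MITF targets (adjusted p = 0.0227), cAMP response (0.00344), matrix (0.0048) and keratinocyte lists (0.00085), but not the fibroblast and macrophage lists. The cause of the sign changes was not tested. Of 1652 values of the 118 genes named by the rule, 1611 kept direction and call, 36 lost the call and 2 gained it. Without Rrp9 and Rrp12, an alternative chosen after seeing the data, the ribosome biogenesis list had a median of 0.02. The simulated recovery of 1.5-fold changes, 68 of 100, came from counts in which few genes changed. With 60.7% of tested genes called here, it does not measure how well small changes were seen. Small changes can still have been missed with 3 libraries per group.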

Other observations

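The tests of explanations in this part, the counts of other splits included, were all set down after the results had been seen, and genes named here outside the rule were chosen after their values were seen. Of 24 tested genes taken by symbol (heat shock protein genes, Dnajb1 and the heat shock regulator Hsf1), which were no fixed list and had no set test, 13 were higher with iBRD9, 4 were lower and the median was 0.34. Besides Hsp90aa1, the constitutive chaperone gene Hspa8 rose from 472 ± 221 to 1489 ± 161 CPM (1.66), Hspa4l from 57.9 ± 0.419 to 128 ± 5.45 CPM (1.14), and Hsph1 (1.03), Hspa1b (1.12) and Dnajb1 (0.80) rose as well. The mitochondrial chaperone gene Hspa9 fell from 2365 ± 588 to 824 ± 24.3 CPM (-1.52), and Hspb8 (-0.69), Hspd1 (-0.45) and Hspa4 (-0.27) were the others that fell. Hsp90ab1, the close relative of Hsp90aa1, rose by 0.34 on the log2 scale (adjusted p = 0.0463), a call lost when any library but DMSO replicate 1 was left out (0.22 without DMSO replicate 3).

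Among single genes outside the lists, picked for their falls and not tested as a group, Slc6a9, a glycine transporter gene, fell from 76.1 ± 16.9 to 10.0 ± 1.88 CPM (-2.91), Gpt2 from 393 ± 80.6 to 61.9 ± 11.1 CPM (-2.66), and the proline synthesis gene Aldh18a1 from 434 ± 115 to 81.9 ± 12.8 CPM (-2.40). The serine synthesis gene Psph (-2.21), the neutral amino acid transporter gene Slc1a4 (-2.26), Bcat1 (-2.42) and Eif4ebp1 (-2.50) also fell. The monoglyceride lipase gene Mgll fell from 676 ± 62.6 to 93.0 ± 6.63 CPM (-2.86). Across all tested genes the median log2 fold change was 0.53 for the 1420 genes with a mean log2 CPM below 0 and -0.15 for the 722 above 8.

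The real split of the libraries was 1 of 10 possible, so no share of splits under 0.05 can be had. The real value and the highest of the other splits were 8262 and 0 for called genes, 8878 and 246 for genes at an unadjusted p under 0.05, 4057 and 0 for genes higher, 4205 and 0 for genes lower, 1280 and 0 for genes at least 2-fold higher, 742 and 0 for genes at least 2-fold lower, and 0.54 and 0.28 for the size of the melanin list's median; in each case 1 split, the real one, gave a value as large. For the number of called lists, 3 of the 10 splits gave at least the real 6, and the highest other gave 12, when DMSO replicate 1 was set together with iBRD9 replicates 2 and 3. Each of the other splits sets 2 libraries of a treatment with 1 of the other. Part of the treatment difference then stays between its groups, so its calls are not calls under no change. The rest falls within its groups and widens their spread, which lowers the number of genes called. The 0 called genes of these splits therefore cannot serve as a measure of chance.

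The genes named for ribosomal RNA, Rrp1, Rrp1b, Rrp7a, Rrp8, Rrp9, Rrp12, Rrp15, Rrp36 and Rrnad1, were all low in the DMSO libraries (Rrp1 17.1 ± 2.13 against 198 ± 1.58 CPM). The loci that collect ribosomal RNA reads, Gm26917 (4.08), Gm42418 (3.18) and Lars2 (2.39), were lower there as well. A general rise of ribosome biogenesis genes is argued against by the list of MYC targets and ribosome biogenesis. Its other 18 members had a median log2 fold change of 0.0166 and none exceeded 0.62 (Nop2). These members include MYC targets of other roles, such as Cdk4 (0.25), Odc1 (0.17) and Srm (-0.44). For Rpl12 (3.40), the near-identical copy Gm10275 had 1101 reads beside 24030 of Rpl12 with iBRD9. At that ratio 95.1 would be needed beside the 2076 of Rpl12 with DMSO, where 0 were seen. A rise of intact Rpl12 mRNA is argued against only if the copy takes the same share of reads in both groups, which was not tested. A candidate explanation is that a filter meant for ribosomal RNA removed reads from the DMSO libraries before counting. No such filter is recorded in the sources used here, and the named genes were grouped by symbol, not by sequence, so their reads need not resemble ribosomal RNA. The gap of 1.05 (log2) between the lowest named gene and the highest other list member restates the observation and does not test this explanation. Outside the list, the exosome genes Exosc5 (2.89) and Dis3 (2.14), whose symbols lack such a name, also lay above the lowest named gene (Rrp8, 1.67). Exosc8 (0.48) was the highest of the other tested genes named Exosc, so the current symbol alone does not mark the pattern. Alternative names of these genes were not considered. Processing and treatment cannot be told apart here, because any such step would follow the groups, and whether the rise of Hsp90aa1, which has no such name, has the same source was not tested and stays open.

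DMSO replicate 1 lay towards the iBRD9 libraries: across 10294 genes its difference from DMSO replicate 2 correlated with the iBRD9 mean minus DMSO replicate 3 (Pearson r = 0.64, Spearman rho = 0.65), against 0.10 for DMSO replicate 2 minus 3 with the iBRD9 mean minus replicate 1; genes are not independent replicates. An iBRD9 library under a DMSO label is argued against, as the 378 genes at least 2-fold lower with iBRD9 than in the other DMSO libraries, at a mean of at least 16 CPM, had moved a median fraction of 0.362 of the way (quartiles 0.182 and 0.492), and Tyr 0.0524. The 356 genes at least 2-fold higher had moved a median fraction of 0.2675 (quartiles 0.109 and 0.416). Taken in the same way, the median for genes that fell was -0.125 for DMSO replicate 2 and -0.196 for DMSO replicate 3. RNA of iBRD9 cells mixed into the library is argued against as the whole cause, since it needs the same fraction for all genes and 7 cholesterol synthesis genes with at least as large a difference had moved 0.795 of the way (quartiles 0.629 and 1.24), or 1.12 for the 12 with a log2 difference of at least 0.5. Another culture state of that sample may account for the pattern and cannot be told apart from other causes, because no label records one. No biological explanation within the design was tested, since the library belongs to its group by label.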
